A study of Homo sapiens with 24 samples.

How the data were processed

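Expression was measured by mRNA sequencing in 24 libraries of the line HUES6, 3 for each of 8 groups (genotype WT or KO, at 0, 3, 6 and 48 h of induction). The groups were taken from the labels. The deposited gene table holds 57820 genes as CPM, that is reads scaled by the authors to the total of each library and not divided by gene length, although its name also mentions TPM. Each column was checked to be whole multiples of the value of 1 read, with 99.7% to 100% of values whole within 0.1 read, and the reads recovered in this way numbered 29896358 to 50451910 per library. The second deposited table holds counts per transcript, given by the authors with no normalization, and its totals were 22.1% to 26.4% of the recovered reads. Reads shared between transcripts appear to be left out of it: ACTB had 2 to 22 transcript counts against 68844 to 242165 recovered reads, and the 37 mitochondrial transcripts had 0. The sample labels name the genome build hg38 and DESeq2, and the aligner and annotation release were not given in the sources used here. The header of the gene table is shifted by 1 cell. With the shift undone, 24 of 24 libraries correlated best with the transcript counts of their own name (r from 0.714 to 0.894 across genes), against 0 with the header as it stands.

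Gene symbols came from GENCODE 29 and were found for 51996 gene identifiers (89.9%). A test by edgeR on counts had been planned before the data were examined. As the unit of the gene table was CPM, limma (3.58.1, in R 4.3.3) with a trend on log2(CPM + 0.25) was used in its place, and edgeR (4.0.16) on the recovered reads became an alternative. CPM values were divided by TMM factors computed from the recovered reads. Genes with too few reads were removed by filterByExpr (minimum of 10 reads, 15 in total), which left 19835. All 8 groups entered 1 fit with no covariate. The 13 comparisons were KO against WT at each hour, each later hour against 0 h in each genotype, and the interaction at 3, 6 and 48 h. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. On this log scale the pseudocount understates changes of genes with low levels.

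The comparisons, gene lists, rule for named genes and part of the alternatives were set before the data were examined. Camera with a preset correlation of 0.01 tested 26 lists in 7 comparisons. The lists were pluripotency, primitive streak, cardiac and lateral plate mesoderm, paraxial mesoderm, definitive endoderm, amnion and trophoblast, neuroectoderm, fibroblast and stroma, WNT pathway targets, BMP pathway targets, NODAL and activin pathway, FGF and ERK response, epithelial, mesenchymal, contractile and actin cytoskeleton, cytosolic ribosomal proteins, translation initiation factors, ribosome biogenesis, p53 targets, integrated stress and unfolded protein response, cell cycle, hypoxia and glycolysis, mitochondrially encoded transcripts, immediate early genes, the chromosome 20q11 region and imprinted genes. Named genes were RBPMS and RBPMS2, and the 6 largest positive and 6 largest negative called changes in each of 4 comparisons (KO vs WT at 0 h and 48 h, WT at 48 h against 0 h, and the interaction at 48 h) or the 3 largest in each of the others. These needed a symbol, a log2 change of at least 1, at least 5 CPM in a group and, for a comparison of groups, no overlap between libraries. Up to 4 members of each list with the smallest adjusted p, and a fixed set of stem cell and germ layer markers at 48 h, were named as well.

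The alternatives set before the data were examined were RLE and upper-quartile factors, DESeq2 (1.42.0), no filter (38005 genes), a filter of at least 5 CPM in 3 libraries (12376 genes), only the groups compared, a replicate block, an estimated correlation for the lists, and each library left out in turn. The alternatives chosen after the data were seen were edgeR on the recovered reads, edgeR on transcript counts summed per gene (17701 genes), pseudocounts of 0.1 and 1, CPM as deposited, array weights, the 3 libraries that stood apart left out together, and WT 0 h library 1 alone kept of its group. In simulated data limma found 46.3%, 85.1% and 100% of genes changed by 1.5, 2 and 4 times. It made 7 false calls among 161 (4.35%), against 11.9% in DESeq2. A list moved by 1.4 times had adjusted p = 1.08e-32, and 0 of 25 unmoved lists were called. This does not cover real lists, where an estimated correlation ended 49 calls. Replicate libraries differed by more than sampling noise (chi-square per gene from 3.27 to 158.5). A library with no read allowed up to 0.0595 to 0.1003 CPM (3 reads). Ratios for genes with 1 to 3 reads have a 95% counting interval, and both cover counting error only. The result of 1 gene in the interaction at 48 h is not reported here. Transcript results other than for RBPMS were left out, as those counts miss most reads. Tables and figures used Python 3.11, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.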

Results

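The series followed a short time course of mesoderm induction in HUES6, a human embryonic stem cell line kept in FTDA medium. Induction used the growth factor BMP4 and CHIR, an inhibitor of the kinase GSK3 that activates WNT signalling, per the labels. Stranded mRNA libraries came from cells labelled wild type (WT) or knockout (KO) of RBPMS, which encodes an RNA-binding protein. Both genotypes were sampled at 0, 3, 6 and 48 h, with 3 libraries per group. The whole reads behind the gene table were 46369507, 40050702 and 36778750 by library number for WT at 0 h and 39529324, 40063495 and 38119546 for KO at 0 h. At 3 h they were 46082296, 41756699 and 39821793 for WT and 38899614, 38862979 and 46273312 for KO. The 6 h libraries held 44798204, 50451910 and 39742879 for WT and 42668743, 46737473 and 29896358 for KO. At 48 h the totals were 40136236, 38729308 and 44000430 for WT and 37634403, 49093513 and 44391700 for KO. A count of 0 allowed up to 0.0595 to 0.1003 CPM (reads scaled to the library's total), the value of 3 reads. This floor covers counting error only. Levels below are means in CPM as deposited, with their SD and n = 3. Counts of a list are of its measured members, and those in parentheses were adjusted over the list alone. Changes are log2 changes with their standard error, from limma unless another tool is named. The labels do not say that libraries of a group came from separate cultures, so each p-value measures only the spread between these samples. That spread was pooled over all groups, though WT 0 h replicates differed most. With only the groups compared, 6 h had more KO against WT calls than 0 h.

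The targeted gene, RBPMS (ENSG00000157110.11), lies on the plus strand of chromosome 8, from 30384479 to 30572261 in the genome build hg38 (GRCh38, GENCODE 29). Its mRNA was not lower in the libraries labelled KO at 0 h, so its level did not check the label. Levels by library were 155, 121 and 130.2 CPM in WT and 158, 153 and 153 CPM in KO at 0 h. At 48 h they were 104, 95.5 and 95.4 CPM in WT and 87.7, 80.6 and 92.5 CPM in KO. The difference between KO and WT was 0.23 ± 0.076 at 0 h (adjusted p = 0.0406), -0.16 ± 0.076 at 3 h (0.326), -0.0928 ± 0.076 at 6 h (0.812) and -0.14 ± 0.076 at 48 h (0.293). The call at 0 h ended without WT 0 h library 2 (adjusted p = 0.231) or 3 (0.139). It also ended without KO 0 h library 1 (0.108), 2 (0.105) or 3 (0.082), and edgeR on the recovered reads did not make it (0.0526). RBPMS fell after induction in KO libraries at 3 h (-0.59 ± 0.076, adjusted p = 4.3e-07), 6 h (-0.48 ± 0.076, 6.27e-06) and 48 h (-0.80 ± 0.076, 7.77e-09), and in WT libraries at 3 h (-0.20 ± 0.076, 0.0265) and 48 h (-0.43 ± 0.076, 4.72e-05). The WT call at 3 h ended without WT 0 h library 1 (0.185) or WT 3 h library 1 (0.0792) or 2 (0.0621).

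Some RBPMS transcripts had their highest counts in KO libraries of 3 h and 6 h. RBPMS-219, a protein-coding transcript that starts at 30387064, had 13 to 25 counts in those 6 libraries, 0 to 1 in the WT libraries and 0 to 2 in the KO libraries of 0 h and 48 h. RBPMS-207, which starts at 30387208, had 23 to 55 counts in the same 6 libraries against 0 to 17 in WT libraries and 4 to 14 in the KO libraries of 0 h and 48 h. These are deposited transcript counts, which left out most reads, and their difference was not tested. The paralog RBPMS2 (ENSG00000166831.4, minus strand of chromosome 15, from 64739892 to 64775587) rose in WT libraries at 6 h (0.33 ± 0.12, 0.0181) and in KO libraries at 3 h (0.30 ± 0.12, 0.0281) and 6 h (0.43 ± 0.12, 0.00222). The WT call ended without WT 0 h library 1 or 3 (adjusted p from 0.0538 to 0.0953), and that of KO at 3 h without KO 0 h library 1 or 2 or KO 3 h library 3 (adjusted p from 0.0506 to 0.711). Both also ended with RLE factors, in DESeq2 and with only the groups compared. RBPMS2 fell between 0 h and 48 h in WT libraries (-0.77 ± 0.12, adjusted p = 6.92e-06) and in KO libraries (-0.38 ± 0.12, 0.00773). At 48 h it stood at 59.2 ± 4.24 CPM in KO and 47.5 ± 4.42 CPM in WT, a difference of 0.36 ± 0.12 (adjusted p = 0.045). That call ended without WT 48 h library 2 (0.0967) or 3 (0.165). It also ended without KO 48 h library 1 (0.0768), 2 (0.0858) or 3 (0.184). The transcript counts gave the opposite sign for RBPMS2 in KO vs WT 48h (-0.78), in WT 48h vs 0h (1.63) and in KO 48h vs 0h (0.74). Its differences were -0.0287 ± 0.12 at 0 h (0.906), 0.19 ± 0.12 at 3 h (0.443) and 0.0769 ± 0.12 at 6 h (0.929).

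**Figure D1:**
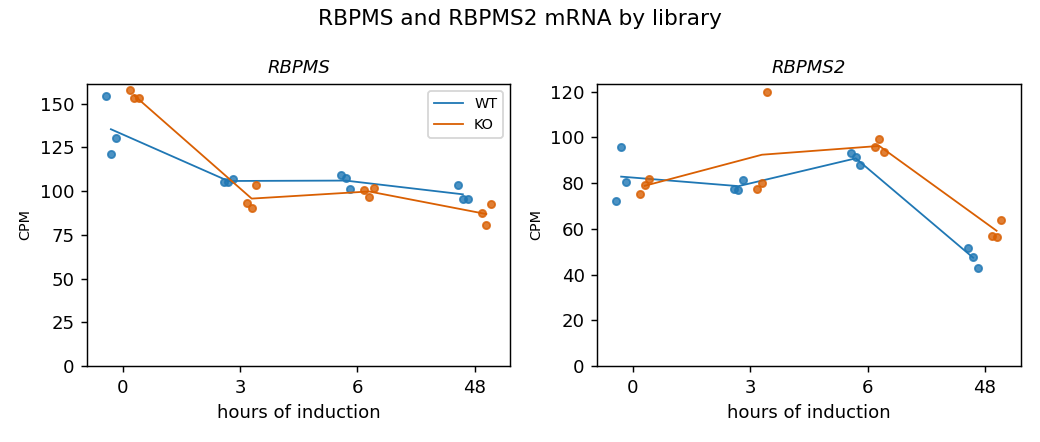
Level of RBPMS and of its paralog RBPMS2 (CPM as deposited, vertical axis) by hour of induction (horizontal axis), with 1 point per library and lines through the means of the WT and the KO groups. RBPMS stood between 80.6 and 158 CPM in all 24 libraries, and its KO libraries were not below the WT libraries at 0 h.

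Hour of induction separated the libraries most. The leading component of all tested genes held 48.6% of the variance and the next 28.0%. In 3 groups, 1 library stood apart from its mates (Pearson r across genes, which are not independent replicates). WT 0 h library 1 had r = 0.975 to 0.978 with its mates, which had r = 0.996 with each other, and its nearest library was KO 0 h library 3 (r = 0.987). Its share of reads from mitochondrially encoded genes was 4.64%, against 7.22% and 7.36% in its mates. KO 3 h library 3 and WT 48 h library 3 were the others. Their deviation from mates (SD 0.456 and 0.373) correlated with GC percent (r = 0.402 and 0.425) and gene length (r = 0.38 and -0.393). KO 0 h 1 and 3 and WT 6 h 2, not apart, had r as strong with GC percent (-0.488, 0.48 and 0.477) at lower SD (0.214, 0.181 and 0.158).

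The comparison at 0 h asks what differed between the KO and WT labels before induction. Genes of the hypoxia and glycolysis response were higher in KO libraries: 14 higher of 20 (19 over the list alone). PFKFB4, an enzyme that sets the rate of glycolysis, stood at 124 ± 4.73 CPM in KO and 44.2 ± 14.2 CPM in WT (1.57 ± 0.14, adjusted p = 2.61e-07). ANKRD37, KDM3A and PFKFB3, known targets of hypoxia-inducible factors, were higher by 1.53, 0.77 and 0.80. BHLHE40 (ENSG00000134107.4), a transcriptional repressor induced by low oxygen, rose to 85.6 ± 7.29 CPM from 12.8 ± 4.0 CPM (2.79 ± 0.16, adjusted p = 1.36e-10). Targets of p53 were lower, with 10 lower of 24 (13 over the list alone). Among these were the cell cycle inhibitor CDKN1A (-1.10 ± 0.16, 5.44e-05) and TIGAR, which lowers glycolytic flux (-1.01 ± 0.15, 0.000115). The hypoxia list had adjusted p = 4.32e-13, but adjusted p = 0.065 with an estimated correlation. The p53 list had adjusted p = 3.32e-06, but adjusted p = 0.157 with an estimated correlation.

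A further 6 lists were called at 0 h. NODAL and activin pathway genes gave 5 higher of 15 (8 over the list alone), with adjusted p = 0.0012, but adjusted p = 0.152 with an estimated correlation. Among them were the secreted antagonist CER1 (1.15 ± 0.0965) and the co-receptor gene TDGF1 (0.42 ± 0.0898). Pluripotency genes gave 6 higher and 1 lower of 25 (11 higher and 2 lower), with adjusted p = 0.00404, but adjusted p = 0.28 with an estimated correlation. DPPA2 stood at 0.76 ± 0.0926 and NANOG at 0.62 ± 0.11. The telomere-binding factor gene TERF1 was lower (-0.42 ± 0.0867), but the transcript counts gave the opposite sign (0.66 for TERF1 KO vs WT 0h). Ribosome biogenesis genes, lower on balance, gave 2 higher and 10 lower of 29 (2 higher and 11 lower), with adjusted p = 0.00103, but adjusted p = 0.484 with an estimated correlation. The integrated stress and unfolded protein response gave 2 higher and 9 lower of 23 (3 higher and 12 lower), with adjusted p = 0.000892, but adjusted p = 0.445 with an estimated correlation. Cell cycle genes gave 1 higher and 10 lower of 32 (2 higher and 11 lower), with adjusted p = 0.0012, but adjusted p = 0.445 with an estimated correlation. Translation initiation factors gave 1 higher and 8 lower of 42 (2 higher and 12 lower), with adjusted p = 0.00407, but adjusted p = 0.445 with an estimated correlation. Within the stress list DDIT4, an inhibitor of mTORC1 also induced by hypoxia, went the other way (1.80 ± 0.19, adjusted p = 1.72e-06). The other 18 lists were not called.

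Among the largest single differences at 0 h were MT1H, a metallothionein that binds metal ions (3.01 ± 0.30), the clock regulator gene BHLHE41 (2.62 ± 0.42), ABHD12B (2.41 ± 0.16) and the neuritin gene NRN1 (2.01 ± 0.27), all higher. TEX13B (-2.03 ± 0.27), the linker histone gene H1-2 (-1.78 ± 0.34), the BMP target ID3 (-1.58 ± 0.25) and the neurotensin gene NTS (-1.56 ± 0.15) were lower. In total 1630 genes were higher and 1420 lower (53.4% higher, but 43.0% with CPM as deposited). With only the groups compared in the fit they were 122 and 48. Single libraries moved these counts. Without WT 0 h library 1 they were 3423 and 3249, without WT 0 h library 2 901 and 657. They were, without KO 0 h library 1, 986 and 759, without KO 0 h library 2 1008 and 824, and without WT 0 h library 3 930 lower. Without WT 0 h library 1 the pluripotency (adjusted p = 0.335) and NODAL (0.238) calls ended and mitochondrially encoded transcripts were called lower (0.0433). With that library alone kept of its group the mitochondrial list was called higher (0.00184), as were immediate early genes (0.00955), and the calls for hypoxia and glycolysis (0.0997), p53 targets (0.0968), cell cycle (0.0968), translation initiation factors (0.187), stress response (0.729) and ribosome biogenesis (0.802, direction reversed) ended.

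Early in induction, at 3 h and 6 h, some imprinted genes, expressed from a single parental copy, were among the largest differences. MEG3 (ENSG00000214548.10), a long noncoding RNA, stood at 0.0717 ± 0.0181 CPM in KO and 135 ± 10.3 CPM in WT at 3 h, and at 0.0718 ± 0.0438 and 91.4 ± 13.9 CPM at 6 h (adjusted p = 7.65e-17 and 2.68e-16). PEG3 (ENSG00000198300.8) had 1 read over the 3 KO libraries of 3 h against 35.8 ± 0.454 CPM in WT, a ratio of 4440 lower (95% counting interval 797 to 175400). At 6 h it had 2 reads over the KO libraries against 43 ± 3.72 CPM in WT, 2565 times lower (710.0 to 21180). NNAT, a small membrane protein gene, was lower at 3 h (-4.30, adjusted p = 1.31e-13). The noncoding RNA MEG8 was at 0 in the KO libraries of both hours, at least 10.2-fold lower at 3 h and at least 5.95-fold lower at 6 h against the floor of 3 reads per library. The MEG8 call at 6 h ended without WT 6 h library 1 or 2 or any single KO 6 h library (adjusted p from 0.0528 to 0.0822). At 6 h the imprinted list gave 1 higher and 4 lower of 24 (the same), with adjusted p = 0.0136. At 3 h it gave 1 higher and 4 lower of 24 (2 higher and 4 lower), with adjusted p = 0.0558, and was called without WT 3 h library 2 (0.0284) or 3 (0.0456) or KO 3 h library 3 (0.0331), and without the 3 libraries that stood apart (0.0151).

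Other genes nearly silent in KO libraries of 3 h and 6 h included MT1G, a metallothionein (0.213 ± 0.173 CPM against 59.7 ± 3.42 CPM in WT at 3 h, adjusted p = 8.37e-17 at 3 h and 3.87e-16 at 6 h). COL1A2, a fibrillar collagen gene, was lower by a log2 change of -3.06 ± 0.16 at 3 h and -2.96 ± 0.16 at 6 h. ZFP42, a pluripotency marker, stood at 24.3 ± 1.84 CPM in KO and 126 ± 1.84 CPM in WT at 3 h (-2.37 ± 0.18, adjusted p = 3.3e-09), and DPPA2 was lower at 3 h (-1.31 ± 0.0926) and 6 h (-1.03 ± 0.0926). The pluripotency list at 3 h gave 3 lower of 25 (4 over the list alone), with adjusted p = 0.0213, but adjusted p = 0.425 with an estimated correlation. That call ended without KO 3 h library 1 (0.0788). At 6 h the pluripotency list gave 2 lower of 25 (3 over the list alone), with adjusted p = 0.0136, but adjusted p = 0.403 with an estimated correlation. In 21 genes, MEG3 and MT1G among them, every KO library of 0 h and 48 h had at least 5 CPM and every KO library of 3 h and 6 h at most 0.5 CPM. In the WT libraries 0 genes met this, and the rule was chosen after these values were seen. Higher in KO at both hours were KCNAB1, a potassium channel subunit gene (1.39 ± 0.23 and 1.36 ± 0.23), and CEP85L, a centrosomal protein gene (1.36 ± 0.23 and 1.36 ± 0.23).

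**Figure D2:**
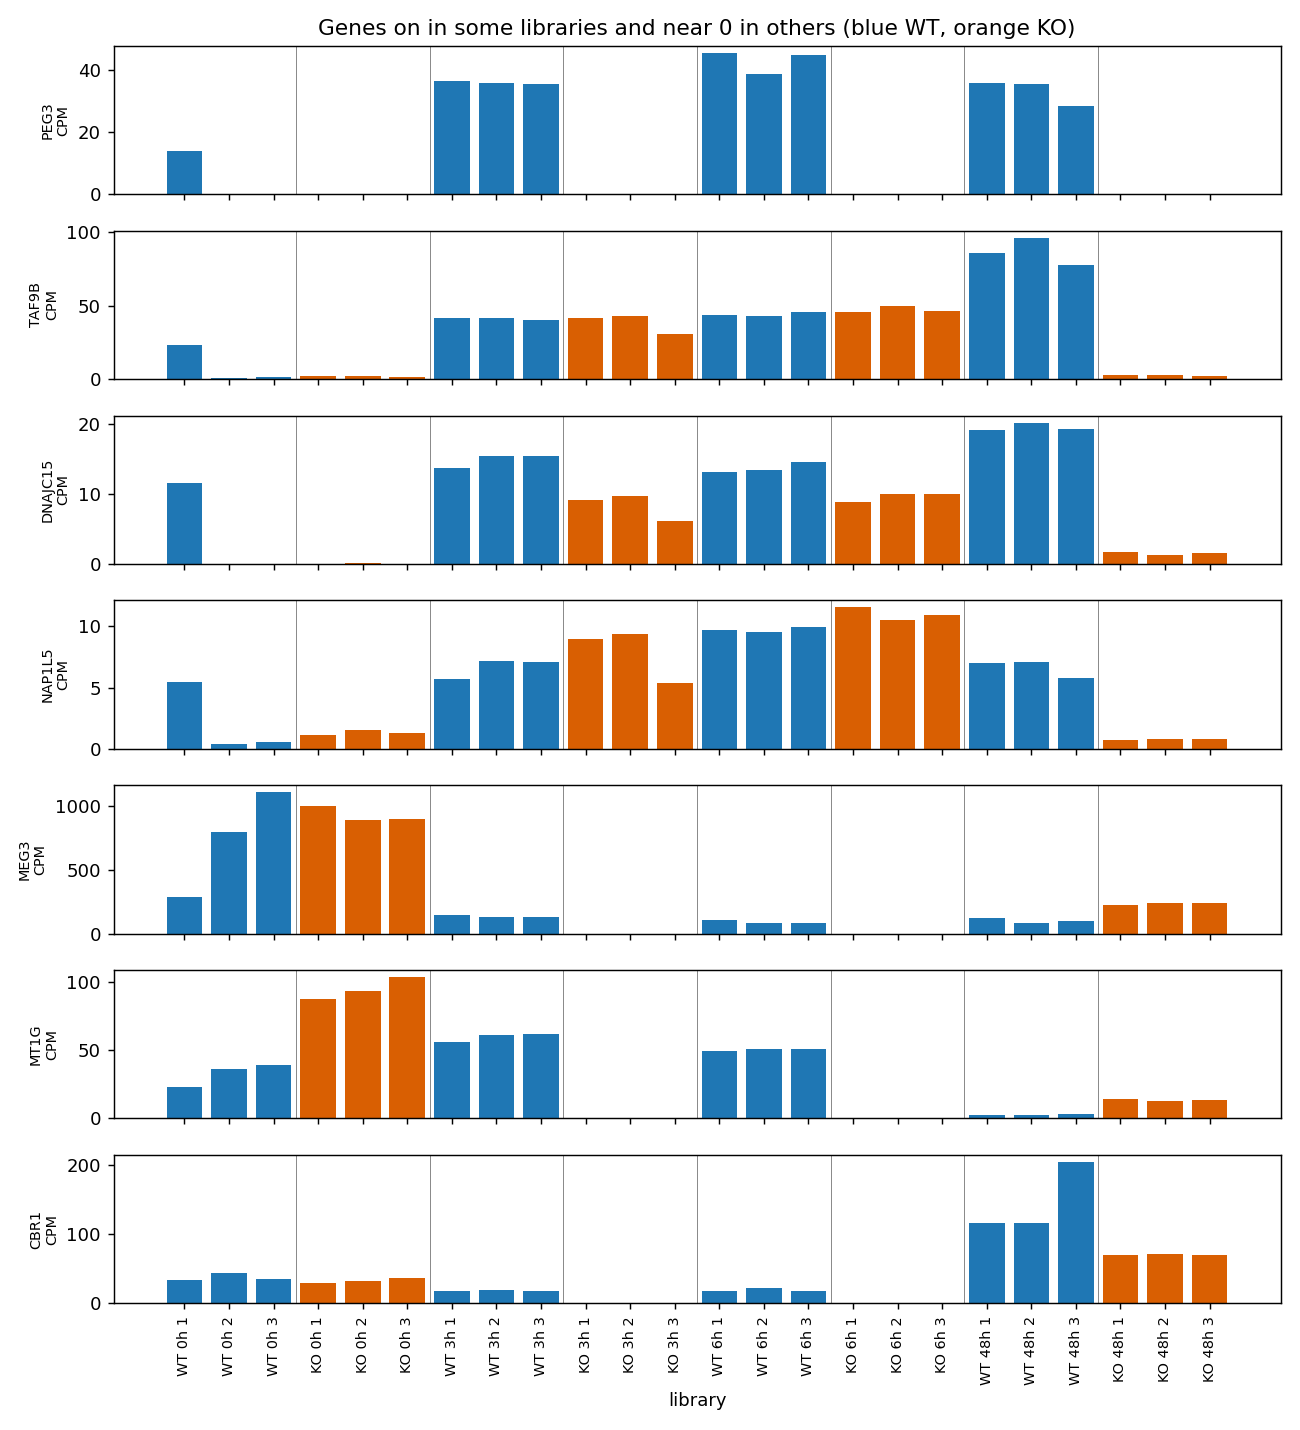
Level (CPM as deposited, vertical axis) of 7 genes in each of the 24 libraries, as bars grouped by genotype and hour. MEG3 stood at 82.2 CPM or more in the WT libraries of 3 h and 6 h and at 0.1 CPM or less in the KO libraries of those hours, while the KO libraries of 0 h and 48 h had at least 226 CPM.

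Immediate early genes, transcription factors induced within minutes of a stimulus, were higher in KO libraries at 3 h, with 7 higher of 25 (13 over the list alone) and adjusted p = 8.53e-10, but adjusted p = 0.229 with an estimated correlation. EGR3 was at 26 ± 9.12 CPM in KO and 10.6 ± 1.4 CPM in WT (1.22 ± 0.20, adjusted p = 0.000354), and the AP-1 subunit gene JUND at 0.93 ± 0.17 (0.00145). This list was not called at 6 h (adjusted p = 0.882), and the change between the hours was not tested. BMP pathway targets, higher on balance at 3 h, gave 0 called of 18 (1 higher over the list alone, 5 at an unadjusted p under 0.05 in limma, 1 called by edgeR and 2 by DESeq2), with adjusted p = 0.0145, but adjusted p = 0.528 with an estimated correlation. That call ended without KO 3 h library 2 (0.0902). At 6 h BMP targets gave 0 called of 18 (1 higher over the list alone, 3 at an unadjusted p under 0.05 in limma, 1 called by edgeR and 1 by DESeq2), with adjusted p = 0.04, but adjusted p = 0.725 with an estimated correlation. This call ended without WT 6 h library 1 (0.0835) or 3 (0.106) or KO 6 h library 1 (0.0799) or 2 (0.158). Cytosolic ribosomal protein genes, lower on balance at 3 h, gave 0 called of 79 (0 over the list alone, 13 at an unadjusted p under 0.05 in limma, 0 called by edgeR and 0 by DESeq2), with adjusted p = 1.19e-08, but adjusted p = 0.84 with an estimated correlation. That call rested on KO 3 h library 3 (adjusted p = 0.552 without it, with the direction reversed). Without the same library the contractile (0.000259) and fibroblast (0.00103) lists were called lower at 3 h, and without KO 3 h library 1 the mitochondrially encoded transcripts were called lower (0.00908).

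At 6 h, 3 further lists were lower on balance. Contractile and actin cytoskeleton genes gave 2 lower of 23 (the same), with adjusted p = 0.0174, but adjusted p = 0.725 with an estimated correlation. They included calponin, CNN1 (-0.77 ± 0.10, adjusted p = 2.59e-05). The stress response list gave 2 lower of 23 (3 over the list alone), with adjusted p = 0.0161, but adjusted p = 0.725 with an estimated correlation. It included DDIT4 (-1.03 ± 0.19). Both calls ended without KO 6 h library 3 (contractile 0.058, stress 0.058). Targets of p53 gave 0 called of 24 (3 lower over the list alone, 5 at an unadjusted p under 0.05 in limma, 0 called by edgeR and 0 by DESeq2), with adjusted p = 0.04, but adjusted p = 0.725 with an estimated correlation. They lost the call without WT 6 h library 2 (0.0583) or 3 (0.0526) or KO 6 h library 1 (0.06) or 3 (0.07). No primitive streak gene was called at 3 h or 6 h, but single genes of other mesoderm lists were. The primitive streak list at 3 h gave 0 called of 15 (0 over the list alone, 0 at an unadjusted p under 0.05 in limma, 0 called by edgeR and 0 by DESeq2), with adjusted p = 0.12. EOMES, a T-box regulator of the streak, stood at 0.26 ± 0.13 (0.349). At 6 h the streak list gave the same counts as at 3 h, with adjusted p = 0.882. The cardiac list gave 2 higher and 1 lower of 24 (2 higher and 2 lower) at 3 h, with adjusted p = 0.729, and 1 lower of 24 (the same) at 6 h, with adjusted p = 0.882. The paraxial list gave 1 lower of 13 (1 higher and 1 lower) at 3 h, with adjusted p = 0.859, and 1 lower of 13 (2 over the list alone) at 6 h, with adjusted p = 0.179. At 3 h NKX2-5 (1.09 ± 0.18) and FOXC1 (1.09 ± 0.24) were higher and KDR (-0.71 ± 0.12, but 0.60 for KDR KO vs WT 3h in the transcript counts) and CDX4 (-0.85 ± 0.20) lower, and at 6 h KDR (-0.75 ± 0.12) and CDX4 (-1.01 ± 0.20) were lower. The 3 h calls ended for FOXC1 without WT 3 h library 1 or 3 or KO 3 h library 2 (adjusted p from 0.0524 to 0.0886), and for CDX4 without WT 3 h library 2 or 3 or KO 3 h library 1 (adjusted p from 0.0515 to 0.084), and for both with only the groups compared (0.0659 and 0.0574), as did NKX2-5 KO vs WT 3h (0.0857). Over all genes, 154 were higher and 388 lower at 3 h, and 100 higher and 399 lower at 6 h. With only the groups compared in the fit, 76 were higher at 3 h, and 1052 higher and 1702 lower at 6 h. The 154 became 73, 67 or 72 without WT 3 h library 1, 2 or 3, 247 without KO 3 h library 2 and 81 without KO 3 h library 3. The 100 became 52 to 58 without any single library of 6 h. The differences at 3 h and 6 h correlated across genes (r = 0.729, Spearman's rho = 0.343). Those at 3 h and 48 h did not (r = -0.0506), nor did those at 0 h and 3 h (r = -0.0431), 0 h and 6 h (r = -0.0735) or 6 h and 48 h (r = -0.00427). Between 0 h and 48 h r was 0.248, and 0.0935 without the 3 libraries that stood apart.

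The comparison at 48 h asks how the labels differed once mesoderm genes were on. Genes of the primitive streak and of paraxial mesoderm, which forms the somites, were lower in KO libraries, and pluripotency genes were higher. TBXT (ENSG00000164458.5), the T-box gene that marks the streak, stood at 57 ± 3.92 CPM in KO and 246 ± 21.7 CPM in WT (-2.06 ± 0.13, adjusted p = 2.37e-10). MSGN1 (ENSG00000151379.3), a regulator of presomitic mesoderm, was at 0.266 ± 0.169 CPM in KO and 6.92 ± 2.36 CPM in WT (-3.73 ± 0.21, 3.64e-11). SOX2 (ENSG00000181449.2), a core pluripotency factor, was at 119.5 ± 17.2 CPM in KO and 43 ± 4.11 CPM in WT (1.50 ± 0.12, 6.81e-09). FOXA2 (ENSG00000125798.10), a pioneer factor of endoderm, was higher too, at 49.1 ± 6.38 CPM in KO and 19.9 ± 2.76 CPM in WT (1.33 ± 0.16, 2.96e-06).

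The primitive streak list gave 7 lower of 15 (9 over the list alone), with adjusted p = 5.05e-09. The homeobox gene EVX1 stood at 3.38 ± 0.856 CPM in KO and 42.6 ± 7.32 CPM in WT (-3.53 ± 0.19, 1.82e-11). MESP1, an early regulator of cardiac mesoderm, was at 0.0565 ± 0.0441 and 4.85 ± 3.21 CPM (-3.82 ± 0.27, 1.43e-09) and the ligand gene WNT8A at -1.83 ± 0.15. The call for EOMES (-0.50 ± 0.13, 0.0133) ended without WT 48 h library 3 (0.0555) or KO 48 h library 2 (0.0683). MIXL1, a homeobox gene of the streak, missed the threshold (-0.48 ± 0.16, 0.0572). It was called without WT 48 h library 3 (0.0376), in edgeR (0.0111) and in DESeq2 (0.00987). Paraxial mesoderm genes gave 2 higher and 9 lower of 13 (2 higher and 10 lower), with adjusted p = 6.56e-10. Examples were the caudal homeobox genes CDX1 at -2.85 ± 0.15 and CDX2 at -2.39 ± 0.24 and the Notch ligand gene DLL3 at -1.98 ± 0.27. The cardiac and lateral plate list gave 1 higher and 7 lower of 24 (the same), with adjusted p = 0.0061, but adjusted p = 0.0651 with an estimated correlation. It included the ligand gene WNT5A (-2.17 ± 0.18), FOXF1 (-1.71 ± 0.23), FOXC1 (-1.47 ± 0.24) and the atrial myosin light chain gene MYL7 (-1.65 ± 0.19). HAND1 was at 0.0347 ± 0.0421 CPM in KO and 0.442 ± 0.262 CPM in WT (-1.18 ± 0.23, 0.00112). GATA4 (-0.29 ± 0.20, 0.419), GATA6 (-0.0497 ± 0.23, 0.935), ISL1 (0.62 ± 0.25, 0.12) and PDGFRA (-0.28 ± 0.15, 0.261), further mesoderm markers, were not called, except ISL1 without KO 48 h library 2 (0.0312).

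Pluripotency genes gave 17 higher of 25 (19 over the list alone), with adjusted p = 3.71e-20. NANOG was at 118 ± 3.44 CPM in KO and 49.5 ± 7.57 CPM in WT (1.30 ± 0.11, adjusted p = 1.59e-08), DPPA2 at 1.61 ± 0.0926, POLR3G at 1.44 ± 0.12, USP44 at 1.11 ± 0.0864 and POU5F1 at 0.48 ± 0.11 (0.00401). The definitive endoderm list gave 4 higher of 12 (the same), with adjusted p = 0.000391. Examples were the chemokine receptor gene CXCR4 at 2.04 ± 0.20, the receptor gene KIT at 0.99 ± 0.0954 and FOXA1 at 1.22 ± 0.21, while SOX17, an endoderm regulator, was not called (0.25 ± 0.17, 0.412). NODAL and activin pathway genes gave 5 higher and 1 lower of 15 (6 higher and 1 lower), with adjusted p = 0.00993, but adjusted p = 0.124 with an estimated correlation. LEFTY1, a secreted NODAL antagonist, was at 49.4 ± 1.73 CPM in KO and 7.36 ± 1.0 CPM in WT (2.75 ± 0.32, 1.67e-06). The ligand gene GDF3 was higher too (1.43 ± 0.24), while the activin antagonist FST was lower (-0.67 ± 0.11). WNT pathway targets gave 2 higher and 7 lower of 18 (2 higher and 9 lower), with adjusted p = 2.09e-05. Examples were the antagonist DKK1 at 10.9 ± 0.413 CPM in KO and 48.6 ± 6.3 CPM in WT (-2.08 ± 0.18), the transcription factor genes SP5 (-1.42 ± 0.19) and TCF7 (-0.61 ± 0.099), and MYC in the other direction (0.64 ± 0.0894). RSPO3, which strengthens WNT signalling, was at 1.42 ± 0.485 CPM in KO and 30.1 ± 11.7 CPM in WT (-4.12 ± 0.23, 3.64e-11).

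BMP pathway targets went both ways, with 3 higher and 4 lower of 18 (5 higher and 6 lower) and adjusted p = 0.455. The homeobox genes MSX1 (-1.81 ± 0.25) and MSX2 (-1.19 ± 0.15) and the inhibitor gene ID4 (-0.97 ± 0.13) were lower. The netrin receptor gene UNC5B was higher (0.86 ± 0.15), but -0.49 for UNC5B KO vs WT 48h in the transcript counts. Mesenchymal genes gave 8 lower of 19 (9 over the list alone), with adjusted p = 7.52e-09, but adjusted p = 0.051 with an estimated correlation. Examples were ZEB2 (-2.26 ± 0.21) and SNAI1 (-0.90 ± 0.13), repressors of the epithelial state, and the receptor gene PDGFRB (-1.67 ± 0.14). Contractile and actin cytoskeleton genes gave 6 lower of 23 (the same), with adjusted p = 0.0061, but adjusted p = 0.358 with an estimated correlation. Examples were the myosin light chain gene MYL9 (-1.59 ± 0.12), transgelin, TAGLN (-0.96 ± 0.19), and CNN1 (-0.68 ± 0.10). Epithelial genes gave 3 higher of 18 (5 higher and 1 lower), with adjusted p = 0.174. The adhesion gene EPCAM was at 0.50 ± 0.12 (-1.48 for EPCAM KO vs WT 48h in the transcript counts). The fibroblast and stroma list gave 1 higher and 2 lower of 12 (the same), with adjusted p = 0.69. Its median was 0.13, against a mean of -0.023 and a test direction of lower. Neuroectoderm genes gave 4 higher of 12 (4 higher and 1 lower), with adjusted p = 0.00996, but adjusted p = 0.166 with an estimated correlation. POU3F1 (1.62 ± 0.17), SIX3 (1.33 ± 0.46 CPM in KO and 0.297 ± 0.106 CPM in WT) and the microtubule-binding gene DCX (0.81 ± 0.11) were higher, and PAX6 was not called (0.0718 ± 0.17, 0.862). The amnion and trophoblast list gave 3 higher and 1 lower of 12 (5 higher and 1 lower), with adjusted p = 0.3. GATA3 (-0.41 ± 0.21, 0.23) and TFAP2A (-0.13 ± 0.19, 0.746), markers of these tissues, were not called. FGF and ERK response genes gave 3 higher of 19 (the same), with adjusted p = 0.174. The ERK antagonist SPRY1 was at 0.64 ± 0.0967.

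Among stress, growth and reference groups, p53 targets gave 11 higher and 1 lower of 24 (13 higher and 1 lower), with adjusted p = 5.21e-07, but adjusted p = 0.0561 with an estimated correlation. Examples were RRM2B, a ribonucleotide reductase subunit gene (0.59 ± 0.10), the nuclease gene AEN (0.57 ± 0.10) and TP53INP1 (0.55 ± 0.10). Hypoxia and glycolysis genes gave 4 higher of 20 (5 over the list alone), with adjusted p = 0.00495, but adjusted p = 0.358 with an estimated correlation. Examples were the peptide hormone gene ADM at 1.24 ± 0.15 (-2.29 for ADM KO vs WT 48h in the transcript counts) and PFKFB4 at 0.71 ± 0.14. Ribosome biogenesis genes gave 4 higher of 29 (the same), with adjusted p = 0.00227, but adjusted p = 0.395 with an estimated correlation. WDR12 was at 0.32 ± 0.066. Translation initiation factors gave 3 higher of 42 (2 over the list alone), with adjusted p = 0.174 (0.0188 without WT 48 h library 3). Cytosolic ribosomal proteins gave 0 called of 79 (0 over the list alone, 1 at an unadjusted p under 0.05 in limma, 0 called by edgeR and 0 by DESeq2), with adjusted p = 0.679. The median was 0.00367, against a mean of -0.0158, and this list was called lower without WT 48 h library 1 (0.0307) and higher without library 3 (0.00139). Cell cycle genes gave 3 lower of 32 (the same), with adjusted p = 0.0142, but adjusted p = 0.395 with an estimated correlation. The replication licensing gene MCM5 was at -0.66 ± 0.0977. DESeq2 called 5 cell cycle genes. Immediate early genes gave 3 higher and 1 lower of 25 (the same), with adjusted p = 0.391, and included KLF4 (1.16 ± 0.20). The stress response list gave 1 higher of 23 (the same), with adjusted p = 0.558. Mitochondrially encoded transcripts gave 0 called of 13 (0 over the list alone, 0 at an unadjusted p under 0.05 in limma, 0 called by edgeR and 0 by DESeq2), with adjusted p = 0.679. The chromosome 20q11 region, often gained in stem cell lines, gave 1 lower of 21 (the same), with adjusted p = 0.219. ASXL1 was at -0.47 ± 0.11, and edgeR and DESeq2 called 2 each. Imprinted genes gave 3 higher and 4 lower of 24 (4 higher and 4 lower), with adjusted p = 0.69. PEG3 was at 0 in every KO library of 48 h and at 33.2 ± 4.23 CPM in WT, at least 417-fold lower against the floor of 3 reads per library. NAP1L5, a nucleosome assembly gene, was at -2.70 ± 0.45.

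Among the largest single differences at 48 h were higher levels of CEMIP, a hyaluronan-degrading protein gene (2.85 ± 0.20), ZNF37A (2.69 ± 0.42), the cytochrome P450 gene CYP2B6 (2.57 ± 0.24), FRMPD4 (2.54 ± 0.22) and the G-protein regulator gene RGS4 (2.48 ± 0.20). Lower were TAF9B, a TFIID subunit gene (2.61 ± 0.433 CPM in KO and 86.6 ± 9.16 CPM in WT), MIR924HG (-4.75 ± 0.73) and the pseudogene SLC25A3P1 (-4.22 ± 0.65). In limma 1505 genes were higher and 938 lower in KO libraries at 48 h, with 1052 to 1367 higher and 642 to 847 lower when 1 library was left out. Array weights gave 3268 and 2480, and the transcript counts 446 and 323. The calls for the pluripotency, primitive streak, paraxial mesoderm, definitive endoderm and WNT lists held with an estimated correlation. WT 48 h library 3 stood apart at this hour. Without the 3 libraries that stood apart, 2678 genes were higher and 2097 lower.

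**Figure D3:**
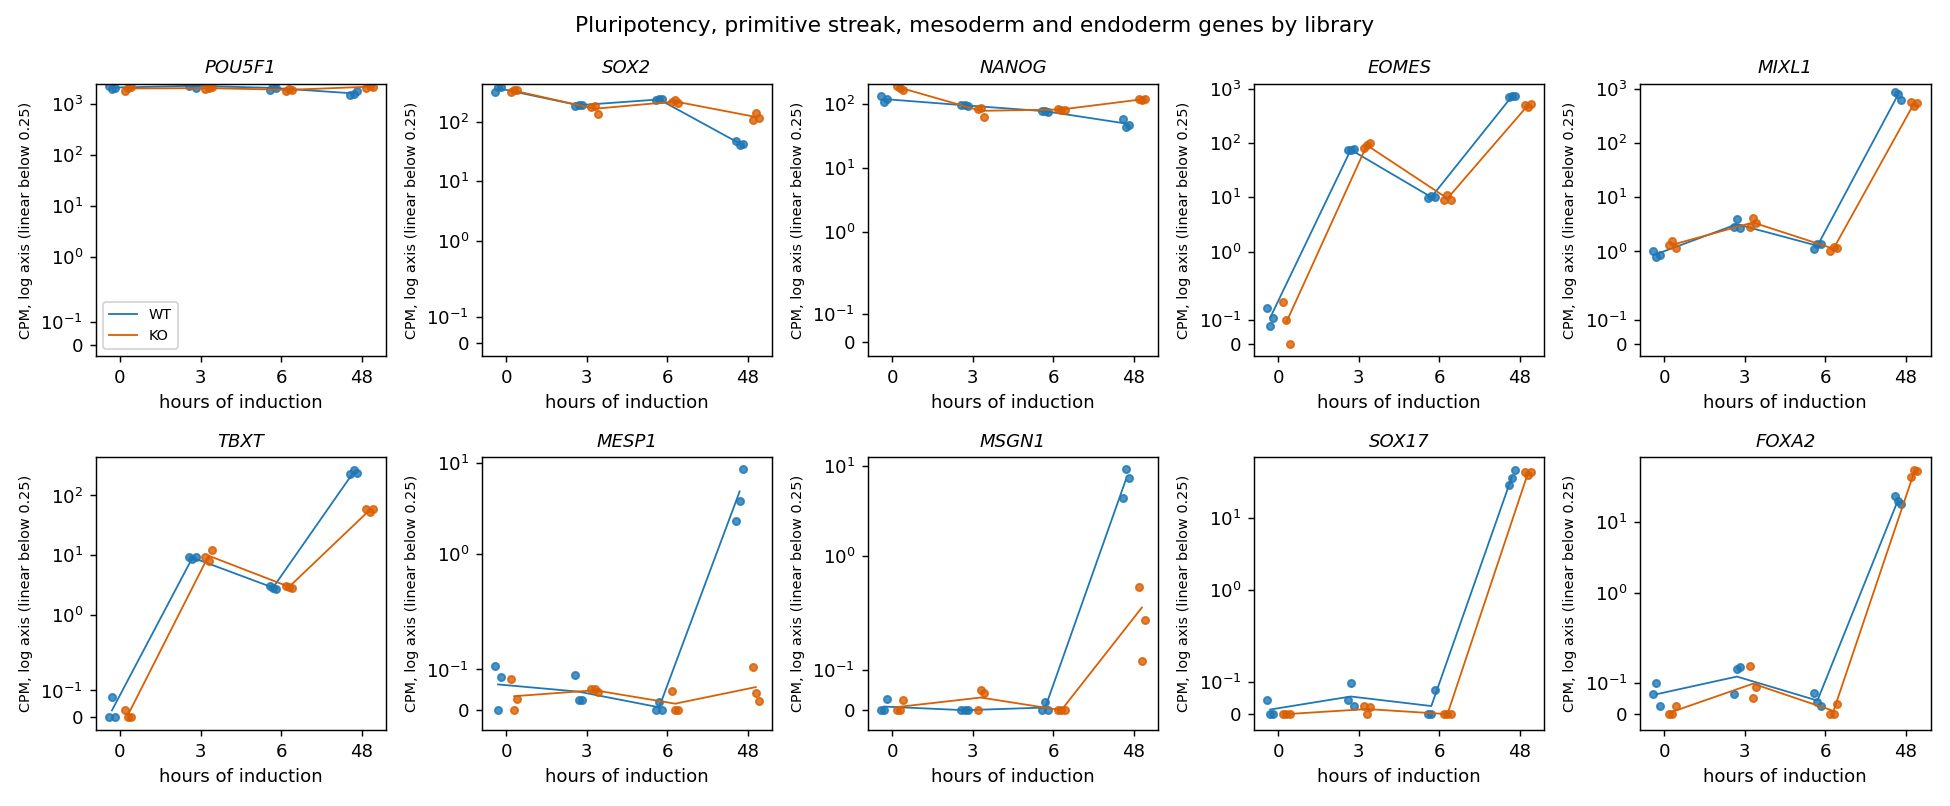
Level of 10 marker genes (CPM as deposited, vertical axis, symmetric log scale) by hour of induction (horizontal axis), with 1 point per library and colours for WT and KO. At 48 h TBXT averaged 246 CPM in WT and 57.0 CPM in KO libraries, and SOX2 averaged 43.0 CPM in WT and 119.5 CPM in KO libraries.

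The response of WT cells to induction was read from the libraries of 3, 6 and 48 h against 0 h. At 48 h nearly all of the primitive streak list was on: 14 higher of 15 (the same). The list had adjusted p = 4.88e-16 and a median log2 change of 6.12. EOMES went from 0.112 ± 0.0381 to 731 ± 14.9 CPM (10.94 ± 0.13, adjusted p = 2.78e-25) and MIXL1 from 0.892 ± 0.126 to 768 ± 124 CPM (9.39 ± 0.16). TBXT had 3 reads over the WT libraries of 0 h and 246 ± 21.7 CPM at 48 h, a ratio of 10090 (95% counting interval 3451 to 48910). Definitive endoderm genes gave 11 higher and 1 lower of 12 (the same), with adjusted p = 5.46e-10. CER1 reached 2260.0 ± 191 CPM (12.18 ± 0.0965) and FOXA2 19.9 ± 2.76 CPM (5.95 ± 0.16). SOX17 went from 2 reads over the 0 h libraries to 36.3 ± 9.12 CPM, a ratio of 2234 (618 to 18450). Pluripotency genes gave 1 higher and 19 lower of 25 (the same), with adjusted p = 5.46e-10. SOX2 changed by -3.04 ± 0.12, PRDM14 by -3.43 ± 0.13 and NANOG by -1.24 ± 0.11. POU5F1 changed by -0.35 ± 0.11 (0.00927), but not past the threshold without WT 48 h library 1 (0.0536).

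Cardiac and lateral plate genes, higher on balance in WT at 48 h, gave 14 higher and 3 lower of 24 (the same), with adjusted p = 0.000464. GATA6 had 3 reads over the 0 h libraries and 93.8 ± 7.74 CPM at 48 h, a ratio of 3853 (1318 to 18680). GATA4 changed by 4.04 ± 0.20, PDGFRA by 5.14 ± 0.15 and FOXC1 by 5.71 ± 0.24. MESP1 reached 4.85 ± 3.21 CPM (3.81 ± 0.27), HAND1 reached 0.442 ± 0.262 CPM from 1 read, a ratio of 54.5 (9.77 to 2151), and ISL1 was not called (0.999). Paraxial mesoderm genes gave 9 higher and 3 lower of 13 (9 higher and 4 lower), with adjusted p = 0.00067, but adjusted p = 0.102 with an estimated correlation. WNT3A rose by 4.57 ± 0.19. WNT pathway targets gave 13 higher and 1 lower of 18 (14 higher and 1 lower), with adjusted p = 3.45e-06. LEF1 was at 4.39 ± 0.18. NODAL and activin genes gave 11 higher and 3 lower of 15 (the same), with adjusted p = 0.000493. The ligand gene NODAL was at 5.45 ± 0.24. Mesenchymal genes gave 17 higher of 19 (17 higher and 1 lower), with adjusted p = 1.57e-08. SNAI1 was at 2.54 ± 0.13. Cell cycle genes gave 14 higher and 2 lower of 32 (the same), with adjusted p = 0.00995, but adjusted p = 0.405 with an estimated correlation. BMP targets gave 10 higher and 2 lower of 18 (12 higher and 2 lower), with adjusted p = 0.00785, but adjusted p = 0.331 with an estimated correlation. Without WT 0 h library 1 the BMP call ended (0.0584). The BMP inhibitor gene SMAD6 was at 1.45 ± 0.14. Targets of p53 gave 3 higher and 17 lower of 24 (the same), with adjusted p = 0.00065, but adjusted p = 0.225 with an estimated correlation. GDF15 fell (-2.25 ± 0.19). Mitochondrially encoded transcripts gave 13 lower of 13 (the same), with adjusted p = 0.000345, but adjusted p = 0.433 with an estimated correlation. Ribosome biogenesis, lower on balance, gave 2 higher and 13 lower of 29 (the same), with adjusted p = 0.00785, but adjusted p = 0.518 with an estimated correlation. That call ended without WT 0 h library 2 (0.0559). With WT 0 h library 1 alone kept of its group it ended too (0.641), as did the mitochondrial call (0.165), and hypoxia and glycolysis was called lower (0.0012). The streak, endoderm, pluripotency, cardiac, WNT, NODAL and mesenchymal calls held with an estimated correlation. The median, mean and test differed in sign in the FGF, translation and hypoxia lists, which were not called. Without WT 0 h library 1 the immediate early list (0.0231, lower) and the 20q11 region (0.0235, higher) were called too. GATA3 (0.48 ± 0.21, 0.0528) and PAX6 (-0.28 ± 0.17, 0.176) were not called, and TFAP2A was (0.64 ± 0.19, 0.0066). GATA3 was called without WT 0 h library 2 (0.0107) or WT 48 h library 1 (0.0345) or 2 (0.0411).

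Among the largest falls in WT at 48 h were IDO1, which degrades tryptophan (-6.79 ± 0.23), the neuronal pentraxin gene NPTX1 (-6.11 ± 0.17) and APELA, a peptide ligand gene (-5.03 ± 0.14). At 3 h the largest rises were in EOMES, CDX1 and CDX2. EOMES reached 75.8 ± 1.24 CPM (7.80 ± 0.13, adjusted p = 1.06e-21). CDX1 reached 31 ± 1.0 CPM from 2 reads, a ratio of 1910 (529 to 15770). CDX2 reached 27.1 ± 2.43 CPM from 1 read, a ratio of 3334 (598 to 131700). Among the largest falls were MYB (-3.38 ± 0.16), STON1 (-3.37 ± 0.30) and RFX3 (-3.28 ± 0.15). At 6 h STON1 (-4.28 ± 0.30), MYCT1 (-3.89 ± 0.24) and LDB2 (-3.83 ± 0.13) fell most, and LAMP5 rose (5.07 ± 0.19). WT libraries had 6013 genes higher and 5028 lower at 3 h, 6586 and 5790 at 6 h, and 5802 and 4968 at 48 h (54.5%, 53.2% and 53.9% higher). With only the groups compared in the fit, 3134 were higher and 3229 lower at 48 h. With CPM as deposited, 43.1% were higher at 3 h and 41.3% at 6 h, and the median of all genes shifted by -0.121 and -0.151 on the log2 scale.

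KO cells responded along the same axis. EOMES went from 0.0923 ± 0.0888 to 503 ± 26.1 CPM (10.54 ± 0.13, adjusted p = 6.47e-25). CER1 rose to 2539 ± 194 CPM (11.24 ± 0.0965), MIXL1 to 533 ± 40.2 CPM (8.42 ± 0.16), and GATA6 to 88.3 ± 9.4 CPM (8.18 ± 0.23). SOX17 rose at least 523-fold and the WNT antagonist DKK4 at least 4153-fold from libraries at 0, against the floor of 3 reads per library. TBXT had 1 read over the 0 h libraries and 57 ± 3.92 CPM at 48 h (ratio 6710.0, 1204 to 265000) and FOXA2 1 read and 49.1 ± 6.38 CPM (5775, 1036 to 228100). The primitive streak list gave 12 higher and 1 lower of 15 (the same), with adjusted p = 1.68e-12. The median was 5.10, or 5.42 with genes at 0 set to their bound. Definitive endoderm gave 12 higher of 12 (the same), with adjusted p = 1.28e-12, a median of 3.96, and 4.10 with those genes at their bound. Pluripotency gave 2 higher and 15 lower of 25 (the same), with adjusted p = 1.45e-05. SOX2 changed by -1.44 ± 0.12 and NANOG by -0.57 ± 0.11, and POU5F1 was not called (0.15 ± 0.11, 0.265). MESP1 (0.11 ± 0.27, 0.757) and GATA3 (0.29 ± 0.21, 0.245) were not called, nor was ISL1 (0.53 ± 0.25, 0.0786), PAX6 (0.52) or HAND1 (0.901). Without KO 48 h library 2 ISL1 had 0.0137. GATA4 (3.21 ± 0.20), PDGFRA (4.75 ± 0.15) and TFAP2A (0.72 ± 0.19) rose.

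A further 9 lists were called in KO at 48 h, none with an estimated correlation. NODAL and activin genes in KO gave 11 higher and 3 lower of 15 (the same), with adjusted p = 0.000675, but adjusted p = 0.0634 with an estimated correlation. WNT targets gave 11 higher and 2 lower of 18 (11 higher and 3 lower), with adjusted p = 0.00142, but adjusted p = 0.064 with an estimated correlation. BMP targets in KO gave 9 higher and 2 lower of 18 (the same), with adjusted p = 0.0255, but adjusted p = 0.45 with an estimated correlation. The cardiac list gave 10 higher and 2 lower of 24 (the same), with adjusted p = 0.011, but adjusted p = 0.114 with an estimated correlation. The mesenchymal list gave 14 higher and 2 lower of 19 (the same), with adjusted p = 0.000226, but adjusted p = 0.264 with an estimated correlation. The cell cycle list gave 16 higher and 1 lower of 32 (the same), with adjusted p = 0.00433, but adjusted p = 0.438 with an estimated correlation. The stress response gave 12 higher and 2 lower of 23 (13 higher and 2 lower), with adjusted p = 0.0271, but adjusted p = 0.546 with an estimated correlation. Hypoxia and glycolysis, lower on balance, gave 2 higher and 11 lower of 20 (the same), with adjusted p = 0.00841, but adjusted p = 0.45 with an estimated correlation. Mitochondrially encoded transcripts, lower too, gave 13 lower of 13 (the same), with adjusted p = 0.000295, but adjusted p = 0.45 with an estimated correlation. In the amnion, neuroectoderm and contractile lists, not called, median, mean and test differed in sign. At 3 h EOMES rose to 92 ± 9.84 CPM, CDX1 to 37.2 ± 3.51 CPM from 1 read (ratio 4377, 786 to 172900) and CDX2 at least 441-fold. Among the largest falls at 3 h were MEG3 (-11.43 ± 0.27), MT1G (-7.68 ± 0.23) and CBR1, a carbonyl reductase gene (-6.60 ± 0.17). At 6 h they were at -11.43 ± 0.27, -7.34 ± 0.23 and -6.79 ± 0.17, and another origin of these libraries stays open. The amino acid transporter gene SLC1A4 (5.78 ± 0.21) and the cadherin gene CDH6 (5.48 ± 0.17) were among the largest rises at 6 h. KO libraries had 6906 genes higher and 6124 lower at 3 h, 7044 and 6619 at 6 h, and 5988 and 4835 at 48 h. At 6 h the median of all genes shifted by -0.12 with CPM as deposited and by 0.115 with upper-quartile factors. The responses of both labels correlated across genes, with r = 0.856 at 3 h, 0.877 at 6 h and 0.867 at 48 h.

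Whether KO and WT responded differently was tested as an interaction, (KO at an hour - KO at 0 h) - (WT at the hour - WT at 0 h). At 48 h the streak and paraxial programs rose less in KO in limma. The paraxial mesoderm list gave 9 lower of 13 (2 higher and 10 lower), with adjusted p = 4.54e-10. Examples were MSGN1 at -3.73 ± 0.29, CDX1 at -2.82 ± 0.21 and DLL3 at -3.0 ± 0.39. The primitive streak list gave 7 lower of 15 (8 over the list alone), with adjusted p = 1.96e-08. EVX1 was at -3.53 ± 0.26, MESP1 at -3.69 ± 0.39, TBXT at -1.99 ± 0.19 and MIXL1 at -0.97 ± 0.23. These genes were near 0 at 0 h. On the recovered reads edgeR did not call TBXT (-0.89), MSGN1 (-4.80), EVX1 (-3.65), CDX1 (-2.91) or MESP1 (-5.59). DESeq2 did not call TBXT, MSGN1, EVX1 or CDX1. Counting intervals of the TBXT rise overlapped (WT 3451 to 48910, KO 1204 to 265000), so a smaller rise is not settled. Of the paraxial and streak lists edgeR called 4 and 2 members and DESeq2 4 and 3. Pluripotency genes fell less, with 11 higher of 25 (14 over the list alone) and adjusted p = 1.37e-08. TERF1 was at 1.4 ± 0.12, POLR3G at 1.73 ± 0.17, SOX2 at 1.60 ± 0.17 and NANOG at 0.68 ± 0.15. WNT targets gave 1 higher and 6 lower of 18 (1 higher and 8 lower), with adjusted p = 2.85e-06. Examples were SP5 at -2.58 ± 0.27, DKK1 at -2.11 ± 0.26 and LEF1 at -1.88 ± 0.25. Targets of p53 gave 15 higher of 24 (20 over the list alone), with adjusted p = 1.94e-14. Examples were CDKN1A at 1.74 ± 0.22, RRM2B at 0.90 ± 0.14, AEN at 0.88 ± 0.15 and TIGAR at 1.14 ± 0.22. These 5 calls held with an estimated correlation (adjusted p of 0.00588, and 0.00628 for WNT). FOXA2 rose more in KO (1.59 ± 0.23, 7.34e-05). Not called were GATA4 (-0.83 ± 0.28, 0.0767, and 0.0267 without WT 0 h library 1), GATA6 (-0.18 ± 0.32, 0.801), PDGFRA (-0.39 ± 0.21, 0.276), SOX17 (0.32 ± 0.24, 0.467), EOMES (-0.41 ± 0.19, 0.204, and 0.0203 without KO 0 h library 3), ISL1 (0.408), GATA3 (0.754), TFAP2A (0.896) and PAX6 (0.788).

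HAND1 (-1.27) and POU5F1 (0.50, 0.048) were called at 48 h. HAND1 lost its call without WT 48 h library 2 (0.0574) or KO 48 h library 1 (0.0542). POU5F1 lost it without any single library of 0 h or 48 h other than WT 0 h library 1 and WT 48 h library 3 (adjusted p from 0.0517 to 0.14). Ribosome biogenesis gave 11 higher and 1 lower of 29 (16 higher and 1 lower), with adjusted p = 2.91e-07, but adjusted p = 0.148 with an estimated correlation. Initiation factors gave 7 higher of 42 (the same), with adjusted p = 0.000241, but adjusted p = 0.148 with an estimated correlation. The stress list gave 4 higher and 1 lower of 23 (8 higher and 2 lower), with adjusted p = 0.000826, but adjusted p = 0.279 with an estimated correlation. Neuroectoderm gave 2 higher of 12 (the same), with adjusted p = 0.0459, but adjusted p = 0.274 with an estimated correlation. Endoderm gave 4 higher and 1 lower of 12 (5 higher and 1 lower), with adjusted p = 0.0358, but adjusted p = 0.148 with an estimated correlation. Mesenchymal genes, lower on balance, gave 1 higher and 6 lower of 19 (1 higher and 9 lower), with adjusted p = 2.91e-07, but adjusted p = 0.098 with an estimated correlation. Hypoxia and glycolysis gave 1 higher and 4 lower of 20 (1 higher and 9 lower), with adjusted p = 4.77e-05, but adjusted p = 0.148 with an estimated correlation. The cardiac list gave 6 lower of 24 (9 over the list alone), with adjusted p = 0.00998, but adjusted p = 0.098 with an estimated correlation. Without WT 0 h library 1 the cardiac call ended (0.0985). The endoderm call ended without WT 0 h library 1 (0.103) or 2 (0.052), WT 48 h library 1 (0.0679) or KO 48 h library 3 (0.051). The neuroectoderm call ended without any of 9 single libraries, that is all but WT 0 h library 1, KO 0 h library 2 and KO 48 h library 1 (0.0524 to 0.148). The ribosomal protein list was called lower without WT 48 h library 1 (0.0246) and the immediate early list higher without WT 0 h library 1 (0.0191). Members called by edgeR and DESeq2 were 3 and 6 in the cardiac list, 1 and 1 in neuroectoderm, 3 and 7 in stress and 2 and 4 in hypoxia. With WT 0 h library 1 alone kept of its group the calls for stress (0.477), endoderm (0.107), neuroectoderm (0.966) and hypoxia (0.81, direction reversed) ended. BMP (0.0339), NODAL (0.0339), contractile (0.0339) and mitochondrial (0.000538) lists were then called lower and epithelial genes (0.0324) higher. Signs differed between median, mean and test in the NODAL and mitochondrial lists and, between median and mean, in the amnion list, none of them called.

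Among the largest interactions at 3 h were MEG3 (-9.35 ± 0.39), MT1G (-8.73 ± 0.32) and MT1H (-8.35 ± 0.42), of which MEG3 fell more in KO and the others rose in WT (1.05 ± 0.23 and 4.10 ± 0.30) and fell in KO, and ID3 (2.35 ± 0.36) and ARC, an activity-induced gene (2.23 ± 0.41), which rose more. At 6 h MEG3 (-8.82 ± 0.39), MT1H (-8.36 ± 0.42) and MT1G (-8.19 ± 0.32) were again among the largest, with TEX13B (2.38 ± 0.38) and CEP85L (2.21 ± 0.33) on the other side. Counts were 738 higher and 1061 lower at 3 h (41.0% higher, but 49.97% with CPM as deposited), 607 and 1076 at 6 h (36.1% higher, but 49.3% with upper-quartile factors), and 882 and 705 at 48 h. They rose without WT 0 h library 1, to 2465 and 2658, 2263 and 2740, and 2813 and 2416. The lowest counts higher with another library left out were 442 without WT 3 h library 1, 354 without KO 6 h library 2 and 550 without KO 48 h library 2.

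**Figure D4:**
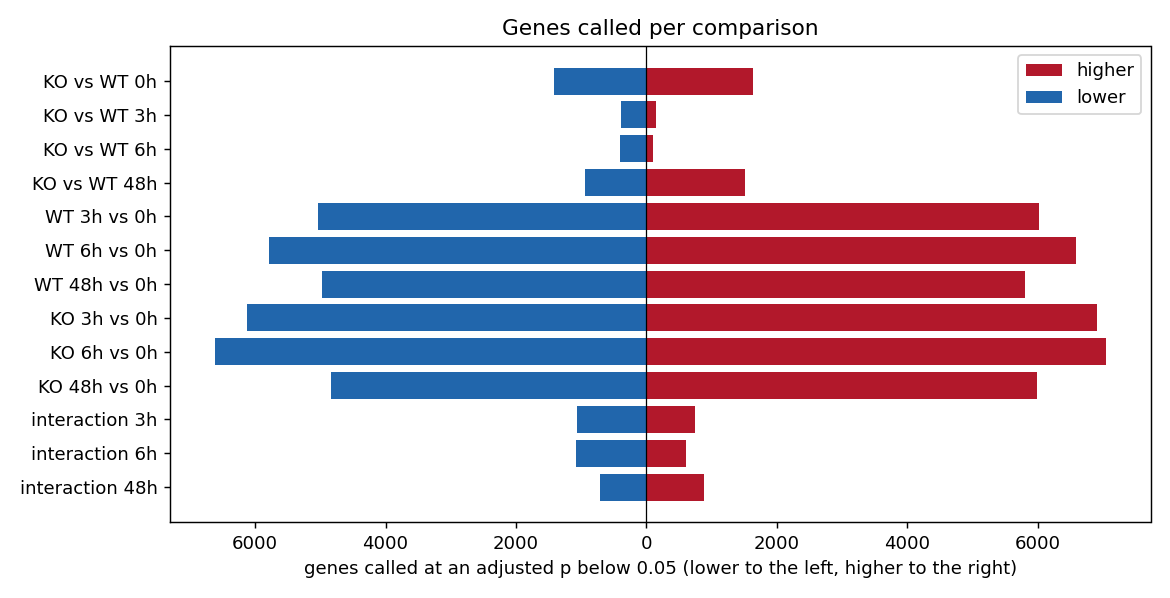
Number of genes called lower (bars to the left) and higher (bars to the right) in each of the 13 comparisons. Calls are by limma (pooled spread) at an adjusted p under 0.05. Responses to induction called between 10770 and 13663 genes, KO against WT between 499 and 3050, and the interactions, (KO at an hour - KO at 0 h) - (WT at the hour - WT at 0 h), between 1587 and 1799.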

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

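The 9 tests of the explanations weighed here were chosen after the results were seen, and the counts of other splits were planned before. All interaction values are differences between the KO and WT responses in log2 units, each past the threshold in the test of the difference itself. At 3 h they were LRRC37A11P (2.43), ID3 (2.35), ARC (2.23), MEG3 (-9.35), MT1G (-8.73), MT1H (-8.35) and RBPMS (-0.39), and at 6 h LRRC37A11P (2.80), TEX13B (2.38), CEP85L (2.21), MEG3 (-8.82), MT1H (-8.36) and MT1G (-8.19). At 48 h the largest changes upward were RGS4 (3.06), SGK1 (2.60), CEMIP (2.44), LRAT (2.37), CYP2B6 (2.35) and FOXQ1 (2.32), and the 7 largest downward were PEG3 (-5.08), TAF9B (-4.25), RSPO3 (-4.01), MSGN1 (-3.73), MESP1 (-3.69), EVX1 (-3.53) and MIR924HG (-3.33). The values of PEG3, TAF9B and NAP1L5 depend on WT 0 h libraries 2 and 3, low in these genes: with library 1 alone kept they were -1.27, -1.47 and, no longer called (NAP1L5 interaction 48h), -0.84. Streak, mesoderm and WNT genes were TBXT (-1.99), MIXL1 (-0.97), HAND1 (-1.27), WNT8A (-1.61), WNT5A (-1.84), FOXF1 (-1.71), FOXC1 (-1.81), BMP4 (-0.75), CDX1 (-2.82), DLL3 (-3.0), CDX2 (-2.35), SP5 (-2.58), DKK1 (-2.11), LEF1 (-1.88) and TCF7 (-0.66). Pluripotency and endoderm genes were POU5F1 (0.50), SOX2 (1.60), NANOG (0.68), TERF1 (1.4), POLR3G (1.73), USP44 (0.90), FOXA2 (1.59), CER1 (-0.94), KIT (0.90) and CXCR4 (1.32). BMP, NODAL and FGF pathway genes were MSX1 (-1.77), MSX2 (-0.99), ID2 (-0.65), HEY1 (1.30), FST (-1.01), LEFTY1 (2.05), GDF3 (1.21), IL17RD (-0.78), SPRED2 (-0.67), FOSL1 (1.02) and SPRY1 (0.45). Neural, epithelial, mesenchymal and contractile genes were SIX3 (1.52), POU3F1 (1.34), CLDN10 (0.58), ZEB2 (-2.41), SNAI1 (-1.14), PDGFRB (-1.08), MMP2 (0.79), CNN1 (-0.86) and SMTN (-0.66). Translation and ribosome genes were EIF5 (0.68), EIF3J (0.55), EIF4A1 (1.27), EIF2S2 (0.60), GNL3 (0.45), WDR12 (0.42), NOP58 (0.76) and UTP15 (0.59). Stress, p53 and cell cycle genes were CDKN1A (1.74), RRM2B (0.90), AEN (0.88), TIGAR (1.14), SESN2 (0.96), BTG2 (0.67), DDIT4 (-1.05), XBP1 (0.46), TRIB3 (0.77), MCM5 (-0.62), MCM6 (0.45), PCNA (0.62) and CDC6 (0.48). Hypoxia, immediate early and imprinted genes were PFKFB4 (-0.86), ANKRD37 (-0.99), ADM (0.80), PDK1 (-0.98), KLF6 (-0.95), EGR3 (-1.29), BLCAP (0.65), NAP1L5 (-2.78) and GRB10 (0.56), beside RBPMS (-0.37). List medians that differed were pluripotency (0.60), primitive streak (-0.85), cardiac mesoderm (-0.11), paraxial mesoderm (-1.46), endoderm (0.23), neuroectoderm (0.14), WNT targets (-0.46), mesenchymal (-0.57), initiation factors (0.19), ribosome biogenesis (0.41), p53 targets (0.70), stress response (0.37) and hypoxia and glycolysis (-0.54). Of these the pluripotency, streak, paraxial, WNT and p53 lists held with an estimated correlation, and the other 8 had adjusted p = 0.098 to 0.279 with an estimated correlation.

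Some of these calls ended when 1 certain library was left out (adjusted p without it). At 48 h ANKRD37 lost its call without KO 48 h library 2 (0.0701). GRB10 (0.0614) and ID2 (0.0547) lost theirs without WT 0 h library 2. Others lost it without any of several single libraries (highest adjusted p): LRRC37A11P at 3 h without 7 (0.08), RBPMS at 3 h without 7 (0.0784), ADM without 6 (0.0774), CDC6 without 7 (0.0952), CLDN10 without 7 (0.108), DDIT4 without 2 (0.0617), EIF2S2 without 8 (0.0883), EIF4A1 without 4 (0.0628), GDF3 without 7 (0.0968), HAND1 without 2 (0.0574), MCM6 without 7 (0.0892), MIR924HG without 11 (0.158), MMP2 without 8 (0.0945), PDK1 without 5 (0.0698), POU5F1 without 10 (0.14), RBPMS without 8 (0.115), SESN2 without 3 (0.0597), SMTN without 8 (0.135), SPRY1 without 9 (0.127), TRIB3 without 10 (0.158), XBP1 without 6 (0.0977). Of the genes at 48 h, edgeR on the recovered reads and DESeq2 both made no call for FOXQ1, RSPO3, MSGN1, EVX1, MIR924HG, TBXT, WNT8A, CDX1, CDX2, MSX1, MSX2, ANKRD37, and edgeR alone made none for PEG3, TAF9B, POU5F1, MESP1, HAND1, FOXF1, SIX3, SPRY1, SMTN, XBP1, TRIB3, MCM6, PDK1, EGR3, NAP1L5. Both turned the direction of WNT8A interaction 48h (0.43 and 0.70).

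Transcript counts of RBPMS-219 (at least 13) and RBPMS-207 (at least 23) were highest in the KO libraries of 3 h and 6 h. This was not tested.

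In 21 genes, MEG3 among them, KO libraries had levels at 0 h and 48 h and almost none at 3 h and 6 h. They lay on 11 chromosomes, and some fell in WT too. Loss of chromosome segments was argued against by the median interaction of 0.000582 in 459 genes within 1 Mb, against -4.2 in the pattern's own genes. Another clone or culture behind the KO libraries of 3 h and 6 h stays open. Without the pattern's genes, KO against WT changes still correlated between 3 h and 6 h (r = 0.669). Those at 3 h did not with 0 h (-0.0399) or 48 h (-0.0381). Of 6 genes named below, 4 reversed the pattern. TAF9B in KO had at most 3.08 CPM at 0 h and 48 h and at least 30.4 between. The hour is confounded with origin. A stop of transcription at induction cannot be told apart either: the genes were chosen for their fall (median 5.39 log2 units at 3 h), and falls of WT genes still transcribed (at most 3.38, in MYB) do not bound decay.

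WT 0 h library 1 stood apart from WT 0 h libraries 2 and 3. As a hypothesis, libraries 2 and 3 may hold cells of the same origin as the KO libraries of 48 h: over 6 genes chosen with no 0 h library (SLC25A3P1, NAP1L5, PEG3, DNAJC15, TAF9B, YPEL3-DT), 12 of 12 values of these libraries lay nearer to KO 48 h than to WT, and each KO library of 3 h and 6 h nearer to WT in 4 (all but SLC25A3P1 and PEG3). Against it, over all genes library 1 came nearer to KO 0 h (highest r = 0.987) than library 2 (0.984) and about as near as library 3 (0.988). An exchange of labels with a KO 0 h library was argued against, since 0 of these genes lay nearer to WT in a KO 0 h library, and GC bias of WT 0 h library 1 by r = 0.112 across genes between GC percent and its deviation. No biological explanation was tested, and the WT comparisons with 0 h rest on these libraries.

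Paraxial mesoderm and primitive streak genes were lower in KO than in WT libraries at 48 h. WT 48 h library 3 alone was argued against, since the paraxial list kept adjusted p = 1.17e-09 without it. A general delay of differentiation cannot be told apart: the definitive endoderm list, higher in KO libraries (adjusted p = 0.019 with an estimated correlation), goes against it, but its interaction lost its call (adjusted p = 0.148 with an estimated correlation), and pluripotency genes, higher in KO libraries (17 of 25, adjusted p = 0.000218 with an estimated correlation), go with it. A difference in clone or culture other than the knockout cannot be told apart either, because 6 genes parted WT libraries of 3, 6 and 48 h from KO libraries of 48 h and genotype and origin are confounded. An effect of the knockout stays open as well.

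Other splits of the same libraries were counted for each comparison. The 3 against 3 designs allow 10 splits, too few for a share under 0.05, and 1 split, the real one, was as large in each: KO vs WT at 0 h called 3050 genes and the best other split 2274, at 3 h 542 and 0, at 6 h 499 and 0, and at 48 h 2443 and 1. The WT responses called 11041, 12376 and 10770, against 154, 153 and 1832, and the KO responses 13030, 13663 and 10823, against 0 in each. The best other split at 0 h put WT 0 h library 1 with KO 0 h libraries 1 and 2. For the interactions 100 splits were drawn. At 3 h 1799 genes against 996 and at 6 h 1683 against 1195 left 1 split as large, the real one. At 48 h 5 of 100 were as large (1587 against 2570), the largest with WT 0 h library 1 beside KO 0 h libraries 2 and 3. Splits mixing genotypes raise the spread, so chance cannot be judged.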

How the results depend on the processing

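The alternatives planned before the data were examined are listed at the start, and the others were chosen after. With the replicate block all 182 list results kept their call and direction, as did 682 of 690 named results. Only 8 of 84 pairs of libraries with the same number had r above 0.1 (range -0.18 to 0.22). No clear pairing by number was seen, but low r cannot exclude one. RLE factors left 679, upper-quartile factors 675, a pseudocount of 0.1 682 and of 1 669 of the named results with their call and direction, edgeR on the recovered reads 641, CPM as deposited 672 and no filter 647. With only the groups compared 521 of 670 did (125 lost the call), in the transcript counts 374 of 583 (173 lost it and 35 reversed), and with WT 0h library 1 alone kept of its group 275 of 347 (65 lost it). Values of 1 library left out are given as lowest to highest: KO vs WT 0h 901 to 3423 higher and 657 to 3249 lower, KO vs WT 3h 67 to 247 higher, KO vs WT 6h 52 to 58 higher, interaction 3h 442 to 2465 higher and 792 to 2658 lower, interaction 6h 354 to 2263 and 795 to 2740, interaction 48h 550 to 2813 and 481 to 2416, and the list cytosolic ribosomal proteins KO vs WT 3h an adjusted p of 4.05e-17 to 0.552, reversed without KO 3 h library 3. Except where stated, the cause was not tested.

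With only the groups compared in the fit, the counts were KO vs WT 0h 122 higher and 48 lower, KO vs WT 3h 76 higher, KO vs WT 6h 1052 higher and 1702 lower, WT 48h vs 0h 3134 higher and 3229 lower, interaction 3h 170 higher and 490 lower, interaction 48h 336 higher and 362 lower. DESeq2 gave KO vs WT 3h 322 higher, interaction 6h 933 higher, and WNT8A reversed in both DESeq2 (WNT8A interaction 48h 0.70) and edgeR on recovered reads (0.43). The stricter filter tests fewer genes and gave KO vs WT 3h 249 lower, KO vs WT 6h 245 lower, KO vs WT 48h 578 lower, WT 3h vs 0h 3261 lower, WT 6h vs 0h 3598 lower, WT 48h vs 0h 2917 lower, KO 3h vs 0h 3775 lower, KO 6h vs 0h 3961 lower, KO 48h vs 0h 2729 lower, with correlations of KO vs WT 3h and KO vs WT 6h 0.821, WT 3h vs 0h and KO 3h vs 0h 0.87, WT 6h vs 0h and KO 6h vs 0h 0.891, WT 48h vs 0h and KO 48h vs 0h 0.895. Array weights, which give libraries that stand apart less weight, gave KO vs WT 0h 4722 higher and 4512 lower, KO vs WT 3h 791 higher and 1071 lower, KO vs WT 6h 968 higher and 1395 lower, KO vs WT 48h 3268 higher and 2480 lower, interaction 3h 3615 higher and 3785 lower, interaction 6h 3739 higher and 4160 lower, interaction 48h 4195 higher and 3680 lower.

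Without the 3 libraries that stood apart in KO vs WT 0h the calls ended for pluripotency 0.355, NODAL 0.163, called higher were ribosomal proteins 0.0456, called lower were mitochondrial 0.0276. In KO vs WT 3h called higher were FGF 0.0124, called lower were fibroblast 0.000357, mesenchymal 0.0172, contractile 0.000211, hypoxia 0.0293, imprinted 0.0151. In KO vs WT 48h called higher were ribosomal proteins 3.29e-10, initiation factors 0.00218. In WT 48h vs 0h the calls ended for BMP 0.114, called higher were 20q11 0.0372, called lower were immediate early 0.0162. In interaction 48h the calls ended for cardiac 0.0832, endoderm 0.223, neuroectoderm 0.0832, called higher were mitochondrial 0.0396, immediate early 0.00762. The counts were KO vs WT 0h 4623 higher and 4789 lower, KO vs WT 3h 580 higher and 1207 lower, KO vs WT 48h 2678 higher and 2097 lower, interaction 3h 3677 higher and 3948 lower, interaction 6h 4043 higher and 3991 lower, interaction 48h 4120 higher and 3590 lower, the cytosolic ribosomal list in KO vs WT 3h reversed (0.711), and correlations were KO vs WT 0h and KO vs WT 48h 0.0935, KO vs WT 3h and KO vs WT 6h 0.785, WT 3h vs 0h and KO 3h vs 0h 0.80, WT 6h vs 0h and KO 6h vs 0h 0.831, WT 48h vs 0h and KO 48h vs 0h 0.81. With WT 0h library 1 alone kept of its group the counts were interaction 3h 1190 higher, interaction 6h 1109 higher, and KO vs WT 0h MYOCD 0.27, RNF43 -0.21, CDH1 -0.0521 reversed, as did ribosome biogenesis in KO vs WT 0h (0.802) and hypoxia in interaction 48h (0.81). In this fit the lone library was assumed to vary like the other groups.

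The transcript counts hold 22.1% to 26.4% of the reads, and gave KO vs WT 0h 396 higher and 446 lower, KO vs WT 3h 45 higher and 163 lower, KO vs WT 6h 13 higher and 156 lower, KO vs WT 48h 446 higher and 323 lower, WT 3h vs 0h 3145 higher, WT 6h vs 0h 3757 higher, WT 48h vs 0h 3576 higher, KO 6h vs 0h 4582 higher, interaction 3h 146 higher and 268 lower, interaction 6h 102 higher and 240 lower, interaction 48h 291 higher and 168 lower. Their signs were opposite for KO vs WT 48h RBPMS2 -0.78, UNC5B -0.49, EPCAM KO vs WT 48h -1.48, ESRP1 KO vs WT 48h -0.0482, PABPC1 KO vs WT 48h -0.0367, GNL3 -0.32, SESN1 -0.54, DDIT4 KO vs WT 48h -1.37, ADM KO vs WT 48h -2.29, WT 48h vs 0h RBPMS2 1.63, GABRP 2.02, ID2 -0.16, TPM4 -0.43, CALD1 -0.28, RPL8 -1.11, RPS2 -0.75, EIF5 -0.51, HERPUD1 WT 48h vs 0h -0.0105, XBP1 -0.36, UBE2C WT 48h vs 0h -0.0771, CCN1 2.01, KO 48h vs 0h RBPMS2 0.74, GABRP 0.53, CALD1 -0.41, RPS15 KO 48h vs 0h -0.0374, RPL8 -0.31, MCM4 KO 48h vs 0h -0.84, KO vs WT 0h TERF1 0.66, CALD1 0.10, GRB10 0.0795, KO vs WT 3h KDR 0.60, interaction 48h ID2 1.42, SPRY1 -0.22, ADM interaction 48h -1.15, GRB10 -0.47. Depth limits levels under 0.0595 to 0.1003 CPM.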

Other observations

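List tests at 3 h and 6 h within each genotype were run after the data were seen, so their results are descriptions. Within 3 h WT cells had raised BMP targets (13 higher and 1 lower of 18, median 2.21, adjusted p = 5.2e-08) and WNT targets (13 higher and 2 lower of 18, median 1.61, adjusted p = 3.49e-05). With them rose primitive streak genes (9 higher and 0 lower of 15, median 1.69, adjusted p = 1.2e-05) and amnion and trophoblast genes (8 higher and 1 lower of 12, median 1.43, adjusted p = 0.000117). Of 18 lists called in WT at 3 h, these 4 held with an estimated correlation (0.0313 for BMP, WNT and streak, 0.0156 for amnion). Ribosome biogenesis (median 0.91, adjusted p = 8.4e-08) and the stress response (median 1.24, adjusted p = 5.2e-08) did not hold (0.16 and 0.0942). At 6 h 11 lists were called in WT, and in KO 16 at 3 h and 11 at 6 h, of which 0 held. In KO at 3 h BMP, WNT, streak and amnion (medians 2.6, 1.94, 1.74 and 0.67) rose too but did not hold (0.0677 each).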
